A study of Mus musculus with 27 samples.

How the data were processed

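Mouse embryonic stem cells (R1) and induced pluripotent stem cells made with 3 factors (H9, called 3F) or 4 factors (19BL, called 4F) were measured on Affymetrix arrays at day 0, day 5 and day 11 of differentiation. There were 3 biological replicates in each of the 9 groups, 27 arrays in all. Per the labels' protocols, the undifferentiated cells were grown on inactivated feeder cells with LIF, and embryoid bodies were formed in serum medium without LIF. Total RNA was purified on columns and labelled as biotinylated cRNA. Per the submitters' processing notes, the deposited values are log2 signals made by RMA, whose version is not given. The deposited log2 values ran from 3.0 to 15.67, with array medians of 5.91 to 6.1, and were used as they stood.

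The table held 45101 probe sets, of which 64 were control probe sets. Symbols were taken from the array annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none. Only probe sets with 1 symbol were used, and each gene was represented by its probe set with the brightest mean over all arrays, which gave 18193 genes, 9010 of them with several probe sets. Symbols were compared with the gene reference by gene identifier (34741 matched) and 0 were changed. Arrays have no read depth. The spread between replicates gives the precision: the SD of the log2 difference between 2 arrays of a group had a median of 0.315 (0.183 to 0.702). No 2 arrays were identical.

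A linear model with 1 mean per group was fitted to all 27 arrays in limma 3.58.1 (R 4.3.3) with empirical Bayes variances. It gave 15 comparisons of 2 groups and 3 comparisons of the change from day 0 to day 11 between lines, 18 in all. P values were adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. Changes are log2 values with the standard error of the limma fit after ±. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

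The comparisons, the alternatives and 29 gene lists were fixed before the data were examined. The lists covered pluripotency, primed epiblast, mesendoderm, cardiac progenitor, cardiomyocyte, smooth muscle, endothelial, erythroid, neural, visceral and definitive endoderm, parietal endoderm, trophoblast, fibroblast and feeder, immune and skeletal muscle genes. They also covered cell cycle, immediate early, p53, glycolysis and hypoxia, fatty acid oxidation, Wnt, BMP and TGF-beta, Notch, imprinted, two-cell-like, germ line, sex-linked, reprogramming factor and extracellular matrix genes. Each list was tested in each comparison with camera, a competitive test in limma, at its preset correlation between genes of 0.01, and p values were adjusted over all 522 tests. Of these, 188 passed. With the correlation estimated from the data for each list, 0 passed, and the lowest adjusted p was 0.175. Counts of called members were also made with p values adjusted over the list alone.

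Named genes followed a rule. Provisional names (1 each in 3F at day 11, 4F against 3F at day 0 and 3F against R1 at day 5) were passed over. For each comparison the 5 largest rises and falls were taken among called genes whose groups did not overlap (comparisons of 2 groups only). To these came up to 4 members of each described list with the largest changes, and 44 genes fixed beforehand. Other genes are marked where they are named. After the results were seen, 22 values of list members were taken out of the text because leaving out single arrays ended their calls, and they are named in the closing section.

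Replicate numbers were checked as possible pairs. In 2 of the 15 comparisons of 2 groups, all 3 same-number correlations of the residuals were over 0.1: 4F against R1 at day 0 (0.48, 0.25, 0.33) and 3F against R1 at day 11 (0.12, 0.49, 0.39). The labels state no pairing, so the main fit used none, and a block was an alternative.

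Alternatives fixed beforehand were median centring, cyclic loess, a filter on dim genes (14698 genes above the 40th percentile of 5.375 in at least 3 arrays), the mean of a gene's probe sets, all probe sets, other thresholds, treat against 1.2-fold, only the compared arrays, a variance trend with robust fitting, array weights, replicate blocks and each array left out in turn. Chosen after the data were seen were quantile normalization, replicate 3 of all groups left out, the 3' minus 5' index of control probe sets as a covariate, and a block with only the compared arrays. Groupings of the same arrays other than the real ones were also counted, 10 for groups of 3 and 100 for differences of changes.

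The fit was tested on simulated data of 18193 genes with 50 changed genes at each of 4 sizes. For 3F against R1 at day 0 it called 41, 49, 50 and 50 of the genes changed by 1.25, 1.5, 2 and 3 on the log2 scale and 4 unchanged genes. For the difference in change between 4F and R1 it called 32, 39, 45 and 50, and 8 unchanged genes. Camera found 1 of 1 shifted list and called 0 of 28 others. This leaves the correlation in real lists open. Probe sets with several symbols or none, and raw array images, were not analysed.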

Results

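Gene expression was measured in 3 mouse pluripotent cell lines before and during spontaneous differentiation. R1 is an embryonic stem cell line. H9 and 19BL are induced pluripotent stem cell lines, made from somatic cells with 3 and 4 reprogramming factors, and are called 3F and 4F here. RNA was taken from undifferentiated cells (day 0) and from embryoid bodies, cell aggregates in which pluripotent cells differentiate without added directing factors, at day 5 and day 11. Each of the 9 groups held 3 arrays of separate biological replicates, 27 arrays in all, and their number limits the precision. The series title concerns the potential of these lines to form heart cells, so genes of heart development, of other cell types and of pluripotency were compared between days within a line and between lines at a day. Changes are log2 changes with the standard error of the fit. A gene is said to have risen, fallen or differed only with an adjusted p under 0.05 and a change of at least 2-fold. Comparisons of 2 groups set 3 arrays against 3, and genes named there as largest changes had no overlap.

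The day of differentiation held 61.85% of the variance between arrays, the line 11.8% and the 9 groups together 84.95%. The first principal component (47.3% of the variance) ran from the day 0 arrays to the day 11 arrays and the second (20.2%) set the day 5 arrays apart. At day 11 the 4F arrays lay at scores of 31.3 to 48.9 on the first component, against 67.0 to 82.8 for R1 and 76.6 to 86.5 for 3F. Replicate 3 of 4F at day 5 lay at -19.3, against -43.5 and -44.2 for the other replicates of its group. The difference between the 3' and 5' control probe sets of Actb and Gapdh, a measure of RNA quality that grows as RNA or its copying is cut short, was highest in 4F at day 11, at 2.69 ± 0.23 (log2, SD, n = 3), against 1.94 ± 0.20 in R1 and 1.55 ± 0.23 in 3F at that day and 1.09 ± 0.07 to 1.45 ± 0.26 at day 0.

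**Figure D1:**
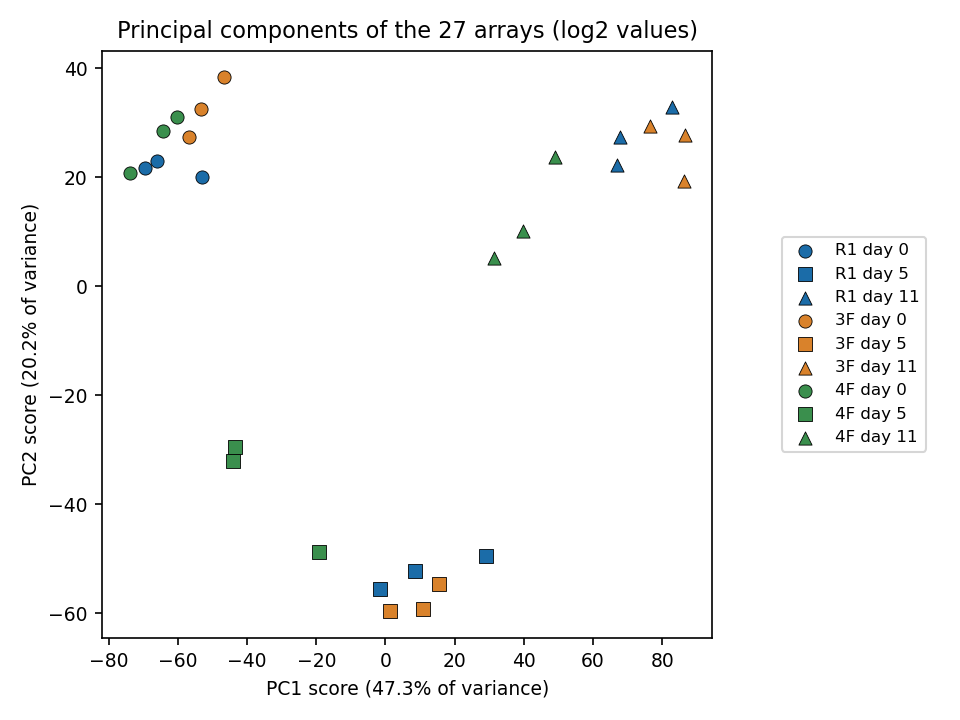
Scores of the 27 arrays on the first (47.3% of variance) and second (20.2%) principal components of the log2 values, with the line given by colour and the day by shape, each point 1 array. The 3 lines lie together at day 0, and on the first component the 4F arrays of day 11 lie at 31.3 to 48.9. At day 5, 4F replicates 1 and 2 lie apart from R1 and 3F (-43.5 and -44.2) and replicate 3 (-19.3) lies between.

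The first question was what each line expressed after 5 days. In R1, genes of early mesoderm and the heart field rose. The apelin receptor gene Aplnr rose by 7.15 ± 1.0 (142-fold, adjusted p = 8.45e-06), Sox17, an endoderm and endothelial transcription factor, by 6.46 ± 0.43 (adjusted p = 3.36e-10), Asb4 by 6.42 ± 0.62, Tdo2 by 5.77 ± 0.74 and the cardiac transcription factor Tbx20 by 5.35 ± 0.66 (adjusted p = 1.82e-06). Of 13 measured primitive streak and mesendoderm genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with Mixl1 at 4.01 ± 0.86, Mesp1, an early marker of cardiac mesoderm, at 3.45 ± 0.71, and Evx1 at 3.29; camera gave an adjusted p of 0.000423 (adjusted p = 0.506 with an estimated correlation). Among 20 cardiac progenitor genes 9 rose and 0 fell, with Hand2 at 4.49 ± 0.45, Gata6 at 3.44 and Gata4 at 2.84 (camera adjusted p = 9.08e-05; adjusted p = 0.213 with an estimated correlation). The VEGF receptor gene Kdr rose by 4.02 ± 0.47. Of 33 cardiomyocyte genes 3 rose (Tnnc1 3.46, Tnni1 1.99, Myl7 1.93) and 3 fell, with Ankrd1 at -2.70, and cardiac troponin T, Tnnt2, was at 1.31 ± 0.65 (adjusted p = 0.13, but 1.87 without day 5 replicate 1, 0.0447, and 1.87 with the index of RNA quality as a covariate, 0.00941). The call of Myl7 (adjusted p = 0.0384) was lost without any single array of R1 at these days except day 5 replicate 3, at adjusted p values of 0.0733 to 0.146. Of 16 genes of BMP and TGF-beta signalling 8 rose, led by Bmp5 (5.18), Bmp2 (4.81) and Msx2 (4.72), and 3 fell. Of 18 imprinted genes 11 rose, with the growth factor gene Igf2 at 4.75, and 1 fell.

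In the same comparison 23 of 26 pluripotency genes fell in R1 and 0 rose, with Nr0b1 at -5.63, Zfp42 at -4.81 ± 0.47, Gdf3 at -4.80 and Tcl1 at -4.22 (camera adjusted p = 1.77e-14; adjusted p = 0.228 with an estimated correlation). Pou5f1, which encodes Oct4, was at -2.61 ± 0.52 (adjusted p = 0.000373). Genes expressed by fibroblasts, which include the feeder cells under the day 0 cultures, also fell: 9 of 16 were lower and 2 higher, with S100a4 at -6.17 ± 0.39, Col5a2 at -4.74 and Col3a1 at -3.45 (camera adjusted p = 0.000233; adjusted p = 0.497 with an estimated correlation). The largest falls were Tm4sf1 at -6.79 ± 0.39, S100a4, Emp1 at -5.91, Lyz1 at -5.85 and Aass at -5.80. Of 14 germ line genes 8 fell, with Mael at -3.58, and of 14 immediate early and stress genes 7 fell and 2 rose. Apart from the mesendoderm list, the counts for R1 at day 5 were equal adjusted over the list alone. In all 2679 of 18193 genes changed, 1205 higher and 1474 lower, and the groups did not overlap at 45.0% of the genes, where chance gives 10%. Quantile normalization of the arrays turned the balance to 1365 higher and 1056 lower.

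3F embryoid bodies at day 5 showed gains in the same lists. Aplnr rose by 7.84 ± 1.0 (228-fold, adjusted p = 2.61e-06), Asb4 by 6.23, Sox17 by 6.19 ± 0.43, the chemokine receptor gene Cxcr4 by 6.11 ± 0.63 and Plac1 by 5.98 ± 0.66. Of 13 mesendoderm genes 7 rose and 0 fell, with Mixl1 at 4.51 ± 0.86, Evx1 at 4.02, Mesp1 at 3.71 ± 0.71 and Lhx1 at 2.07 (camera adjusted p = 0.000189; adjusted p = 0.492 with an estimated correlation). Of 20 cardiac progenitor genes 8 rose and 1 fell, with Tbx20 at 4.50 ± 0.66, Hand2 at 3.89 and Gata4 at 3.85 (camera adjusted p = 3.82e-05; adjusted p = 0.212 with an estimated correlation). Kdr rose by 4.43 ± 0.47. Of 33 cardiomyocyte genes 6 rose and 4 fell, with Tnnc1 at 3.92 ± 0.52, Tnni1 at 2.82, Myl7 at 2.52, Tnnt2 at 2.41 ± 0.65 (adjusted p = 0.00685, but 1.68 and 0.0704 without 3F day 5 replicate 2) and Ankrd1 at -4.75. Of 26 pluripotency genes 22 fell and 0 rose, with Nr0b1 at -6.17, Dppa2 at -5.47 and Zfp42 at -5.43 ± 0.47 (camera adjusted p = 1.13e-15; adjusted p = 0.218 with an estimated correlation), and Pou5f1 was at -2.65. The 16 fibroblast and feeder genes held 13 falls and 0 rises, with S100a4 at -6.43, Col1a2 at -6.01 and Col3a1 at -6.00 (camera adjusted p = 6.49e-10; adjusted p = 0.261 with an estimated correlation). The largest falls of all genes were Tm4sf1 at -7.38 ± 0.39, Anxa1 at -6.86, Ptgs2 at -6.85 ± 0.29, Lox at -6.77 and Emp1 at -6.62. Adjusted over the list alone the counts of these lists were equal. The comparison called 2263 genes, 917 higher and 1346 lower, and 56.7% of all genes had groups that did not overlap (10% by chance).

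4F embryoid bodies at day 5 gained genes of the primed epiblast and the primitive streak. Fgf5, a marker of the post-implantation epiblast, rose by 4.04 ± 0.67 (adjusted p = 0.000163), Ttr, the transthyretin gene of visceral endoderm, by 3.73 ± 0.70, Mixl1 by 3.40 ± 0.86 (adjusted p = 0.00598), Hoxb1 by 3.12 and Vrtn by 2.98 ± 0.29. Of 10 primed epiblast genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), with Fgf5, Sfrp2 at 1.77 and Car4 at 1.75 (camera adjusted p = 0.0111; adjusted p = 0.495 with an estimated correlation). Of 13 mesendoderm genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), with Evx1 at 2.59 (camera adjusted p = 0.00063; adjusted p = 0.518 with an estimated correlation). Mesp1 was at 1.66 ± 0.71 (adjusted p = 0.103), Tbx20 at 0.96 ± 0.66 (adjusted p = 0.334), Kdr at 1.26 ± 0.47 (adjusted p = 0.0603) and Tnnt2 at -0.26 (adjusted p = 0.84). In replicate 3 the levels of Tbx20 and Kdr were 7.90 and 9.79, against 4.19 and 4.23 and 7.07 and 7.06 in the others. Without replicate 3 of all groups Mixl1 was at 1.67 (adjusted p = 0.0519) and Hand1 at 0.94, and with only these 6 arrays Mixl1 (0.0766), Hoxb1 (0.0913) and Evx1 (0.0552) did not pass. Without 4F day 5 replicate 1 or 2, Mesp1 (2.28 and 2.29) and Kdr (1.72, adjusted p = 0.0196 in both) passed, and Kdr also with dim genes left out (0.0497). Of 20 cardiac progenitor genes 1 rose (Hand1, 1.46) and 2 fell, with Tbx18 at -1.81, and of 33 cardiomyocyte genes 0 rose and 1 fell (Ankrd1, -3.97), with the same counts adjusted over the list alone. With the mean of their probe sets Hand1 (0.79) and Tbx18 (-0.99) were under 2-fold. Pluripotency genes fell at 18 of 26 members (19 adjusted over the list alone) and rose at 0, with Klf4 at -2.97, Tet1 at -2.36, Nr0b1 at -2.16 and Nanog at -2.09 ± 0.48 (camera adjusted p = 2.69e-08; adjusted p = 0.363 with an estimated correlation). Pou5f1 was at -0.38 ± 0.52 (adjusted p = 0.673, but -1.14 and 0.0463 with the index). Fibroblast and feeder genes fell at 14 of 16 members (15 adjusted over the list alone), with S100a4 at -5.59, Ccl2 at -5.07 and Dcn at -4.88 (camera adjusted p = 1.77e-14; adjusted p = 0.213 with an estimated correlation). The largest falls were Serpinb2 at -6.91 ± 0.43, Tm4sf1 at -6.76, Ptgs2 at -6.75, Prss23 at -6.64 and Anxa1 at -6.54. The comparison called 1286 genes, 409 higher and 877 lower, with groups that did not overlap at 46.6% of genes (10% by chance), and quantile normalization changed the split to 512 higher and 629 lower.

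By day 11 genes of contracting heart muscle had risen in R1. Tnnt2 rose by 6.01 ± 0.65 (64.3-fold, adjusted p = 1.23e-07), the slow skeletal and fetal cardiac troponin I gene Tnni1 by 4.76 ± 0.45 (adjusted p = 1.78e-08), Tnnc1 by 3.78, Corin by 3.29 and Actc1, cardiac actin, by 2.91. Of 33 cardiomyocyte genes 15 rose and 1 fell, the mean change was 1.24, and camera gave an adjusted p of 0.000991 (adjusted p = 0.364 with an estimated correlation). Nkx2-5, an early cardiac transcription factor, was at 0.36 (adjusted p = 0.251) and Myh6 at 0.69 (adjusted p = 0.482, but 2.05 and 0.00198 without day 11 replicate 3 and 1.83 and 0.00315 with array weights). Of 20 cardiac progenitor genes 13 rose and 0 fell, with Hand2 at 6.13, Tbx20 at 5.82 ± 0.66, Gata6 at 5.11 and Tcf21 at 5.04 (camera adjusted p = 7.6e-07; adjusted p = 0.175 with an estimated correlation). Other tissues rose as well. Endothelial genes rose at 8 of 16 members and fell at 0, with Kdr at 3.29 and Cd34 at 2.73 (camera adjusted p = 0.00221; adjusted p = 0.363 with an estimated correlation). Erythroid genes rose at 5 of 12, led by the embryonic globin gene Hbb-y at 8.03 ± 0.89 (camera adjusted p = 0.0278; adjusted p = 0.535 with an estimated correlation). Immune genes rose at 7 of 10, with Ptprc, the pan-leukocyte marker CD45, at 2.94 ± 0.45 (camera adjusted p = 0.00199; adjusted p = 0.473 with an estimated correlation). Visceral and definitive endoderm genes rose at 8 of 18 (9 adjusted over the list alone), with Afp at 6.01 ± 0.38 and Ttr at 5.80, while 2 fell (camera adjusted p = 0.0018; adjusted p = 0.473 with an estimated correlation). Fibroblast genes, which had fallen by day 5, rose at 11 of 16 members and fell at 3 against day 0, with Lum at 7.71 ± 0.50 and Col3a1 at 4.54 (camera adjusted p = 0.0159; adjusted p = 0.66 with an estimated correlation). Asb4 at 6.94, Prss35 at 6.66 and Colec11 at 6.58 completed the largest rises.

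The falls in R1 at day 11 held pluripotency and cell cycle genes. Of 26 pluripotency genes 25 fell and 0 rose, with Tdgf1 at -6.44, Nanog at -6.43 ± 0.48 (adjusted p = 7.69e-10), Zfp42 at -6.01 and Pou5f1 at -5.44 (camera adjusted p = 2.64e-16; adjusted p = 0.217 with an estimated correlation). Of 17 cell cycle genes 14 fell and 0 rose (camera adjusted p = 1.36e-07; adjusted p = 0.32 with an estimated correlation), and of 10 primed epiblast genes 8 fell and 1 rose (camera adjusted p = 0.00251; adjusted p = 0.445 with an estimated correlation). Aass at -6.57, Morc1 at -6.45 and Eras at -6.37 were the other largest falls. Of 18 imprinted genes 13 rose and 0 fell, with Igf2 at 6.30, Dlk1 at 5.53 and Plagl1 at 4.15 (camera adjusted p = 6.96e-06; adjusted p = 0.274 with an estimated correlation). Apart from the endoderm list, the counts of the lists given for R1 at day 11 were equal adjusted over the list alone. The comparison called 4294 genes, 2077 higher and 2217 lower, with groups that did not overlap at 52.7% of genes (10% by chance). Cyclic loess between arrays moved the split to 2440 higher and 1677 lower.

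The same cardiac lists held the rises of 3F at day 11. Tnnt2 rose by 6.08 ± 0.65 (67.5-fold, adjusted p = 8.19e-08), Tnni1 by 5.82 ± 0.45, Corin by 3.97 and Myh7 by 2.34. Of 33 cardiomyocyte genes 15 rose and 2 fell, with a mean change of 1.17 (camera adjusted p = 0.000246; adjusted p = 0.32 with an estimated correlation). Myh6 was at -0.99 (adjusted p = 0.272). Of 20 cardiac progenitor genes 10 rose and 1 fell, with Hand2 at 5.75, Tcf21 at 4.74 and Gata6 at 4.73 (camera adjusted p = 1.43e-05; adjusted p = 0.207 with an estimated correlation). Of 16 endothelial genes 9 rose and 0 fell, with Kdr at 3.85 and Cd34 at 2.98 (camera adjusted p = 0.000154; adjusted p = 0.251 with an estimated correlation). The embryonic globin gene Hbb-y made the largest rise at 10.26 ± 0.89 (1228-fold, adjusted p = 3.9e-09), before Nell1 at 7.75 ± 0.40, Asb4 at 6.97, the alpha-fetoprotein gene Afp at 6.56 and Hbb-bh1 at 6.53. Of 12 erythroid genes 7 rose and 0 fell (camera adjusted p = 4.45e-05; adjusted p = 0.288 with an estimated correlation), and of 18 endoderm genes 9 rose and 1 fell (camera adjusted p = 0.000723; adjusted p = 0.45 with an estimated correlation). Of 10 immune genes 1 was higher and 3 lower, among them Ctss at -3.24 and Cd68 at -2.40. The mean over that list was -0.33 and the median 0.18 (camera adjusted p = 0.85). Pluripotency genes fell at 25 of 26 members, with Dppa2 at -7.86 ± 0.39, Zfp42 at -7.50 and Nanog at -7.23 (camera adjusted p = 3.45e-15; adjusted p = 0.226 with an estimated correlation). Of 17 cell cycle genes 15 fell, with Mcm3 at -2.59 (camera adjusted p = 2.34e-09; adjusted p = 0.274 with an estimated correlation). Nefl at -6.99 and Fgf4 at -6.90 were also among the largest falls. The counts of these lists were equal adjusted over the list alone. The comparison called 4285 genes, 1373 higher and 2912 lower, with groups that did not overlap at 49.9% of genes (10% by chance). The split was 1997 to 1843 after cyclic loess, 1971 to 1948 after quantile normalization and 1615 to 2480 without day 11 replicate 1.

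4F at day 11 had raised cardiac transcription factors with few contractile genes. Tbx20 rose by 4.76 ± 0.66 (adjusted p = 3.3e-06), Hand2 by 4.68, Gata6 by 3.07 and Isl1 by 2.75, and 12 of 20 cardiac progenitor genes rose while 0 fell (camera adjusted p = 3.27e-06; adjusted p = 0.205 with an estimated correlation). Of 33 cardiomyocyte genes 3 rose and 2 fell (2 and 2 adjusted over the list alone), with Tnni1 at 2.62 ± 0.45 and Tnnt2 at 1.71 ± 0.65 (adjusted p = 0.0388, but 0.82 and 0.314 without 4F day 11 replicate 3, 1.59 and 0.0992 without day 0 replicate 1 and 1.62 and 0.0981 without day 0 replicate 2). The mean change of the list was 0.07 and the median -0.01 (camera adjusted p = 0.418). Actc1 was at 0.59 (adjusted p = 0.576) and Myh6 at -1.70 (adjusted p = 0.0624). Myh6 passed as a fall after median centring (0.0436), with only these 6 arrays (0.000143), array weights (0.00307), a replicate block (0.0262) and without replicate 3 of all groups (0.00154). Tnnt2 did not pass after median centring (0.0545) or quantile normalization (0.0522), with only these 6 arrays (0.0706) or without replicate 3 of all groups (0.187), and was at 5.36 (0.00198) with the index of RNA quality as a covariate. Endoderm genes made large rises, with Ttr at 6.34 ± 0.70, Afp at 5.15 and Rbp4 at 3.73, and 9 of 18 members rose while 0 fell (camera adjusted p = 8.44e-06; adjusted p = 0.308 with an estimated correlation). Hbb-y at 7.34 ± 0.89, Hbb-bh1 at 6.05 ± 1.22, Igf2 at 6.01 and Dlk1 at 5.43 were the other largest rises. With the index as a covariate Hbb-bh1 (5.21, adjusted p = 0.179), Isl1 (1.81, 0.107) and Rbp4 (1.79, 0.171) did not pass. Of 18 imprinted genes 11 rose and 0 fell (camera adjusted p = 4.17e-05; adjusted p = 0.32 with an estimated correlation). All 26 pluripotency genes fell, with Nr0b1 at -5.03, Gdf3 at -4.40, Nanog at -4.21, Pou5f1 at -2.81 ± 0.52 and Zfp42 at -2.56 (camera adjusted p = 3.83e-11; adjusted p = 0.274 with an estimated correlation). Of 17 cell cycle genes 14 fell (camera adjusted p = 1.92e-07; adjusted p = 0.324 with an estimated correlation). The largest falls were Mmp13 at -8.07 ± 0.32, Mmp3 at -7.45, Serpinb2 at -6.76, Ereg at -6.36 and Cxcl5 at -6.12. In every change from day 0, loss of feeder RNA may add to the falls. Apart from the cardiomyocyte list, these counts were equal adjusted over the list alone. The comparison called 3784 genes, 1222 higher and 2562 lower, with groups that did not overlap at 54.9% of genes (10% by chance). The median change of all genes was -0.11, and -0.23 after each array was centred on its median, so falls near that size carry no direction. The split was 1889 to 1537 after cyclic loess and 1653 to 1772 after quantile normalization.

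**Figure D2:**
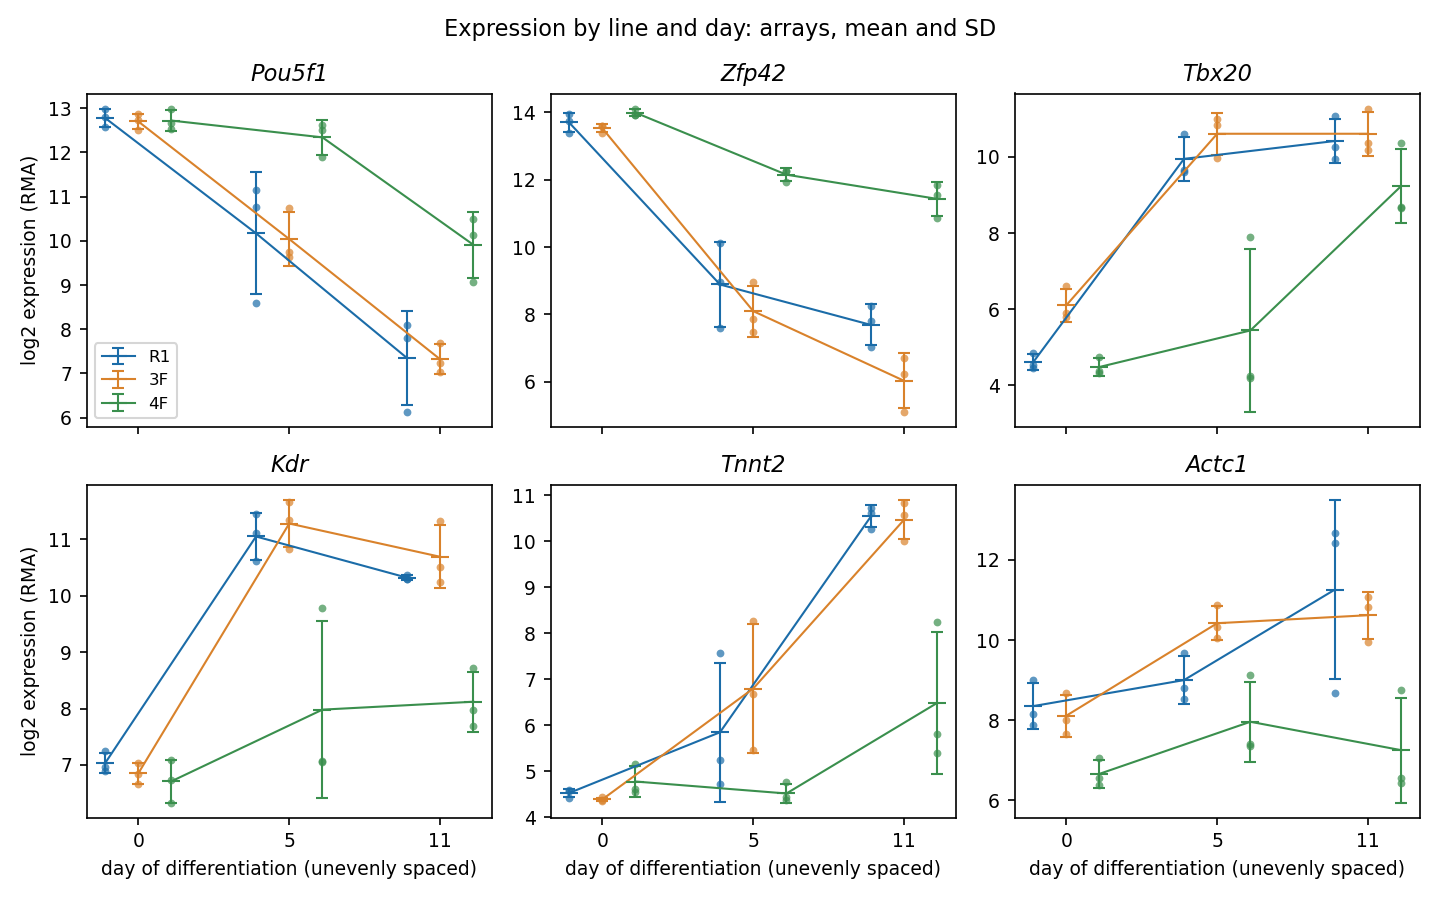
Log2 expression of 6 genes by day (0, 5 and 11) in R1, 3F and 4F, where small points are single arrays and bars are the mean and SD of 3 arrays. Pou5f1 and Zfp42 stayed higher in 4F than in the other lines at day 11, and Tnnt2 reached 10.54 ± 0.24 in R1 and 10.47 ± 0.43 in 3F but 6.49 ± 1.54 in 4F.

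Across genes, the changes of the lines from their own day 0 were correlated, though genes are not independent replicates and no test was made. At day 5 the correlation was 0.87 between R1 and 3F, 0.68 between R1 and 4F and 0.73 between 3F and 4F, and at day 11 it was 0.87, 0.75 and 0.79. Over the genes called in the first line of each pair, the slope of the second line's changes on the first's was 0.94, 0.53 and 0.53 at day 5 and 0.88, 0.65 and 0.70 at day 11. R1 and 3F shared 1596 genes called in 1 direction at day 5 and 3097 at day 11, with 0 and 4 called in opposite directions. R1 and 4F shared 816 and 2399, with 17 and 37 in opposite directions, and 3F and 4F shared 840 and 2635, with 21 and 21.

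At day 0 the 3 lines were compared before differentiation, and unequal feeder RNA may add to any difference. Between 3F and R1, 1 of 26 pluripotency genes differed, Tcea3 at -1.40 (3F minus R1, adjusted p = 0.01, and 0.0669 without R1 replicate 2 or 0.0738 without 3F replicate 3; also 1 adjusted over the list alone), and Pou5f1 was at -0.09 (adjusted p = 0.949). The largest rises in 3F were Rpgrip1 at 4.21 ± 0.32 (adjusted p = 1.38e-08), Ipp at 3.38, Cdc42ep2 at 3.17, Ccdc141 at 2.87 and Pof1b at 2.75. Rpgrip1 and Ccdc141 rest on 1 probe set each: with the mean of their probe sets they were at 0.94 and 0.59, under 2-fold. The largest falls were Gbp2b at -5.42 ± 0.60, Dpys at -5.13 ± 0.28 (adjusted p = 5.72e-11), Fmr1nb at -5.09, Aass at -4.98 and Bcat2 at -3.95. Fibroblast and feeder genes were higher in 3F at 6 of 16 members (13 adjusted over the list alone) and lower at 0, with Pdgfrb at 2.50 ± 0.66 (adjusted p = 0.0248, but 0.155 and 0.128 without R1 replicates 2 and 3 and 0.0608 and 0.134 without 3F replicates 1 and 3; camera adjusted p = 7.6e-09; adjusted p = 0.302 with an estimated correlation). Parietal endoderm and basement membrane genes were higher at 3 of 9 (4 adjusted over the list alone; camera adjusted p = 0.00013; adjusted p = 0.424 with an estimated correlation). Germ line genes were lower at 3 of 14, with the X-linked homeobox genes Rhox6 at -2.76 and Rhox9 at -2.34 (camera adjusted p = 9.41e-06; adjusted p = 0.207 with an estimated correlation). Among 33 cardiomyocyte genes, 1 was higher and 1 lower (Ankrd1 at 1.87 and Myom2 at -1.63; mean -0.04; camera adjusted p = 0.496). Ankrd1 did not pass without R1 replicates 2 or 3 (adjusted p = 0.101 and 0.0781) or 3F replicates 1 or 3 (0.0971 and 0.104), and Myom2 was at -0.83 with the mean of its probe sets. The index as a covariate ended the calls of Ankrd1, Pdgfrb and Tcea3 (1.22, 1.40 and -1.16; adjusted p = 0.199, 0.254 and 0.0933). There were equal counts adjusted over the list alone for this and the germ line list. In all 562 genes differed, 402 higher and 160 lower in 3F, and the groups did not overlap at 29.9% of genes (10% by chance). The count was 1179, 193 and 304 without R1 replicates 1, 2 and 3, and 344 and 204 without 3F replicates 1 and 3. The split was 88 higher and 96 lower without replicate 3 of all groups and 114 to 79 without R1 replicate 2.

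The largest differences between 4F and R1 at day 0 were not grouped by a fixed list. Usp18 was higher in 4F by 4.45 ± 0.52 (adjusted p = 1.43e-05), Ifit1 by 4.11 ± 0.41 (adjusted p = 1.4e-06) and Rtp4 by 3.08, next to the chemokine gene Cxcl5 by 4.10 and the collagenase gene Mmp13 by 4.04 ± 0.32. Gbp2b was lower at -4.13, Aass at -3.63, Fmr1nb at -3.62, Calml4 at -3.10 and Fgf5 at -3.06 ± 0.67 (adjusted p = 0.0134, but 0.068 without R1 replicate 3 and 0.0805 and 0.0569 without 4F replicates 1 and 2). Of the 26 pluripotency genes 2 were higher, with Esrrb at 1.22 (adjusted p = 0.00242, but 0.93 with the mean of its probe sets), and Dppa3 was lower at -1.65 (adjusted p = 0.0123, but 0.0587 without R1 replicate 2 and 0.0939 without 4F replicate 3; 3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00932; adjusted p = 0.664 with an estimated correlation). Pou5f1 was at -0.06 (adjusted p = 0.984). Of 4 sex-linked genes 2, both Y-linked, were lower in 4F, Eif2s3y at -2.81 ± 0.56 (adjusted p = 0.00578) and Uty at -2.20 (adjusted p = 0.00116; the same 2 adjusted over the list alone; camera adjusted p = 0.000742; adjusted p = 0.175 with an estimated correlation). Germ line genes were lower at 2 of 14 (3 adjusted over the list alone), Rhox6 at -2.55 and Rhox9 at -2.19. Fibroblast and feeder genes were higher at 1 of 16, Dcn at 2.15 (3 adjusted over the list alone). No cardiomyocyte gene of 33 differed (0 higher, 0 lower; mean -0.13; camera adjusted p = 0.363), where limma called 204 of all genes and 2390 had an unadjusted p under 0.05. The 204 genes held 117 higher and 87 lower, and 17.1% of genes had groups that did not overlap (10% by chance). The count was 449 without R1 replicate 1, 131 without 4F replicate 1 and 123 at an adjusted p under 0.01. With only these 6 arrays it was 134 (67 higher, 67 lower), and 291 with the replicate number as a block.

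Between 4F and 3F at day 0, Ifit1 was higher in 4F by 4.16, Rtp4 by 4.04 ± 0.27 (adjusted p = 6.12e-09), Usp18 by 3.73 and Xaf1 by 3.60, next to Bcat2 at 3.54. The largest falls in 4F were H2-Q10 at -3.13, Cdc42ep2 at -3.10, the keratin genes Krt8 at -2.83 and Krt19 at -2.66, and Igfbp3 at -2.72 (adjusted p = 0.0146, but 0.0966 and 0.0515 without 3F replicates 1 and 3 and 0.0658 without 4F replicate 2). Pluripotency genes were higher in 4F at 6 of 26 and lower at 1, with Tfcp2l1 at 1.63 (adjusted p = 0.0241, but 0.0588 to 0.125 without any single array of these groups except 4F replicate 3, and 0.67 with the mean of its probe sets) and Dppa3 at -1.63 (adjusted p = 0.00874, but 0.0742 without 4F replicate 3; camera adjusted p = 0.00221; adjusted p = 0.607 with an estimated correlation). Fibroblast and feeder genes were lower in 4F at 2 of 16 (10 adjusted over the list alone; camera adjusted p = 2.45e-05; adjusted p = 0.453 with an estimated correlation). Of 18 imprinted genes 2 were lower, with the noncoding RNA Rian at -1.19 (adjusted p = 0.0171, but -0.82 and 0.138 with the mean of its probe sets, 0.103 without 3F replicate 3 and 0.0812 and 0.0585 without 4F replicates 2 and 3; camera adjusted p = 0.000135; adjusted p = 0.364 with an estimated correlation). Of 4 sex-linked genes 2 were lower, with Uty at -1.96. These counts were otherwise equal adjusted over the list alone. The comparison called 360 genes, 161 higher and 199 lower, with groups that did not overlap at 31.9% of genes (10% by chance). The count was 196 without 3F replicate 3 (110 higher, 86 lower) and 192 without 4F replicate 2 (110 and 82).

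Both induced lines shared 65 genes that differed from R1 in the same direction at day 0, 28 higher and 37 lower, and 3 that differed in opposite directions. Gbp2b, Aass and Fmr1nb were among the largest falls in both. Lists of these sizes drawn independently would share 2.59 higher and 0.765 lower genes. In 100 simulations of unchanged groups a mean of 0.02 (3F) and 0 (4F) genes were called, so the 0 shared decides nothing. The draw leaves out the shared R1 arrays. Since 3 R1 arrays cannot be split evenly in 2, part of the excess may come from the shared controls or be particular to R1. The count was 190 without R1 replicate 1 and 37 without R1 replicate 2.

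At day 5 few genes separated 3F from R1. Rpgrip1 was higher by 2.97 ± 0.32 (adjusted p = 9e-06, but 0.61 with the mean of its probe sets), the glutamine transporter gene Slc1a5 by 2.80 ± 0.15 (adjusted p = 8.26e-11), Amph by 2.78, Zfp429 by 2.61 and Ang by 2.16. Gbp2b was lower at -3.81, Bcat2 at -2.70, Sycp3 at -2.47 (adjusted p = 0.00391), Fmr1nb at -2.46 and Rhox5 at -2.42. Of 14 germ line genes 2 were lower (4 adjusted over the list alone), Sycp3 among them (camera adjusted p = 0.000401; adjusted p = 0.242 with an estimated correlation). The index of RNA quality as a covariate ended the calls of Sycp3 (-1.16, adjusted p = 0.11) and Gbp2b (-2.43, 0.067). Of the heart lineage lists, 0 of 13 mesendoderm, 0 of 20 cardiac progenitor and 0 of 33 cardiomyocyte genes passed in limma, also when adjusted over the list alone, where 68 of all genes passed and 1623 had an unadjusted p under 0.05. Mesp1 was at 0.16 (adjusted p = 0.984), Tbx20 at 0.66 (adjusted p = 0.865) and Tnnt2 at 0.96 (adjusted p = 0.754). The 68 genes held 40 higher and 28 lower, and 25.1% of genes had groups that did not overlap (10% by chance). The count was 39 without R1 replicate 2, 41 without 3F replicate 3 and 220 with array weights (105 higher, 115 lower), and the index gave 30 higher and 56 lower.

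4F and R1 differed at day 5 in the genes of pluripotency, heart progenitors and germ line. Nr0b1 was higher in 4F by 4.30 ± 0.52 (adjusted p = 1.92e-05), Mymx by 4.13, Mael by 4.04 ± 0.33 (adjusted p = 2e-07), Mcf2 by 3.73 and Tcl1 by 3.38. Pluripotency genes were higher at 19 of 26 members (20 adjusted over the list alone) and lower at 0, with Zfp42 at 3.26 ± 0.47, Fgf4 at 3.17 and Pou5f1 at 2.17 ± 0.52 (adjusted p = 0.00672, but 0.0669 without R1 replicate 3; camera adjusted p = 5.93e-17; adjusted p = 0.213 with an estimated correlation). Primed epiblast genes were higher at 5 of 10, with Pou3f1 at 2.34, and lower at 1 (camera adjusted p = 0.000834; adjusted p = 0.385 with an estimated correlation). Germ line genes were higher at 4 of 14 (5 adjusted over the list alone; camera adjusted p = 1.98e-07; adjusted p = 0.175 with an estimated correlation). Tdo2 was lower at -5.33 ± 0.74, Aplnr at -5.14 ± 1.0 (adjusted p = 0.00139), Bmp5 at -4.54, Tbx20 at -4.51 ± 0.66 (adjusted p = 0.000106) and Nrp1 at -4.45. Of 20 cardiac progenitor genes 8 were lower and 0 higher, with Hand2 at -3.76, Gata6 at -1.95 and Gata4 at -1.92 (camera adjusted p = 2.46e-05; adjusted p = 0.207 with an estimated correlation). Kdr was at -3.08 ± 0.47. Of 16 BMP and TGF-beta genes 8 were lower and 2 higher, with Bmp2 at -3.82 and Smad6 at -3.55 (camera adjusted p = 3.63e-05; adjusted p = 0.226 with an estimated correlation). Of 18 imprinted genes 10 were lower and 1 higher, with Igf2 at -3.94 and Cdkn1c at -3.29 (camera adjusted p = 4.22e-09; adjusted p = 0.213 with an estimated correlation). Mesp1 was at -1.83 ± 0.71 (adjusted p = 0.101), but passed at -3.07 (0.000435) without 4F replicate 3, at -2.60 (0.0301) without R1 replicate 3 and at -3.13 (8.04e-05) with array weights. Tnnt2 was at -1.32 (adjusted p = 0.221), and of 33 cardiomyocyte genes Tnnc1 (-3.82) and Tnni1 (-2.12) were lower and 1 was higher. Eif2s3y was at -4.32 ± 0.56 (adjusted p = 3.07e-05). Where not given, counts adjusted over the list alone were equal. The comparison called 992 genes, 421 higher and 571 lower, with groups that did not overlap at 35.0% of genes (10% by chance). Replicate 3 of 4F lay nearer to R1 than its group mates. With only these 6 arrays the calls of Aplnr, Gata4, Gata6, Nrp1, Pou3f1 and Pou5f1 ended (adjusted p = 0.0518 to 0.102).

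Between 4F and 3F at day 5, Mael was higher in 4F by 5.29 ± 0.33 (adjusted p = 6.15e-10), Nr0b1 by 4.63, Dppa2 by 4.44 ± 0.39, Mymx by 4.32 and Mcf2 by 4.14. Pluripotency genes were higher at 18 of 26 (19 adjusted over the list alone) and lower at 0, with Zfp42 at 4.05 and Pou5f1 at 2.30 (camera adjusted p = 1.43e-14; adjusted p = 0.228 with an estimated correlation). Primed epiblast genes were higher at 8 of 10, with Otx2 at 3.77 and Pou3f1 at 3.17, and lower at 1 (camera adjusted p = 7.36e-05; adjusted p = 0.308 with an estimated correlation). Germ line genes were higher at 5 of 14, with the RNA helicase gene Ddx4 at 3.90 (camera adjusted p = 3.28e-09; adjusted p = 0.175 with an estimated correlation). Aplnr was lower at -5.61, Tbx20 at -5.17 ± 0.66 (adjusted p = 1.11e-05), Cxcr4 at -5.04, Pmp22 at -4.76 and Nrp1 at -4.73. Cardiac progenitor genes were lower at 8 of 20 and higher at 0, with Hand2 at -3.73 and Gata4 at -2.48 (camera adjusted p = 1.96e-05; adjusted p = 0.207 with an estimated correlation). In the list of 33 cardiomyocyte genes 7 were lower and 1 higher, with Tnnc1 at -4.24, Tnni1 at -2.46 and Tnnt2 at -2.28 ± 0.65 (adjusted p = 0.0174, but 0.152 without 3F replicate 2, 0.0634 without 4F replicate 1 and 0.0671 without 4F replicate 2). With the index as a covariate Tnnt2 (-0.91, adjusted p = 0.478) and Pou5f1 (1.03, 0.185) did not pass. The mean of the cardiomyocyte list was -0.44 and the median 0.02 (camera adjusted p = 0.299). BMP and TGF-beta genes were lower at 9 of 16 and higher at 2, with Smad6 at -4.31 (camera adjusted p = 8.44e-06; adjusted p = 0.213 with an estimated correlation). Imprinted genes were lower at 10 of 18 and higher at 1, with Igf2 at -4.11 (camera adjusted p = 2.05e-08; adjusted p = 0.218 with an estimated correlation). Where not given, counts adjusted over the list alone were equal. The comparison called 1360 genes, 529 higher and 831 lower, with groups that did not overlap at 45.4% of genes (10% by chance). The split was 522 to 498 with the index.

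At day 11, 3F and R1 differed in genes of immune cells. Ptprc was lower in 3F at -3.22 ± 0.45 (adjusted p = 0.000187), the platelet factor gene Pf4 at -3.0 (adjusted p = 0.00967, but 0.086 and 0.0918 without R1 replicates 1 and 2) and Plek at -2.92. Of 10 immune genes 6 were lower (8 adjusted over the list alone) and 0 higher, with Cd14 at -2.32 (camera adjusted p = 9.41e-09; adjusted p = 0.218 with an estimated correlation). The erythrocyte anion exchanger gene Slc4a1 was higher by 2.91 ± 0.16 (adjusted p = 9.53e-11), the one of 12 erythroid genes to pass (3 adjusted over the list alone; camera adjusted p = 2.99e-05; adjusted p = 0.274 with an estimated correlation). Trbv13-2 at 3.60 ± 0.46, Ang at 3.60 ± 0.19, Galc at 2.89 and Rpgrip1 at 2.65 (0.74 with the mean of its probe sets) were the other largest rises, and Gbp2b at -4.03 and Trap1a at -2.96 were among the largest falls. Among 33 cardiomyocyte genes, 0 were higher and 0 lower, also when adjusted over the list alone, where limma called 185 of all genes and 3512 had an unadjusted p under 0.05. Their mean was -0.11 (camera adjusted p = 0.433), Tnnt2 was at -0.07 ± 0.65 (adjusted p = 0.968), Actc1 at -0.64 and Myh6 at -1.29 (adjusted p = 0.328). Myh6 passed as lower in 3F without R1 replicate 3 (-2.65, adjusted p = 0.00257) and, with Actc1, without replicate 3 of all groups (-1.97 and 0.0107; -1.60 and 0.0129). Of 26 pluripotency genes 2 were lower in 3F (5 adjusted over the list alone), with Dppa2 at -2.07 (adjusted p = 0.00444), and of 14 germ line genes 3 (4 adjusted over the list alone), Rhox6 at -2.40, Rhox9 at -1.70 and Tex19.1 at -1.50. These 3 did not pass with only these 6 arrays, with a replicate block (adjusted p = 0.137, 0.215 and 0.0723) or without (0.376, 0.559 and 0.212). The comparison called 42 higher and 143 lower, with groups that did not overlap at 11.5% of genes, where chance gives 10%, and quantile normalization gave 66 and 130. The count was 115 without R1 replicate 1 or 2 and 360 without R1 replicate 3. It was 146 (63 higher, 83 lower), 512 and 340 without 3F replicates 1, 2 and 3. With these 6 arrays alone it was 10, where Ptprc, Pf4, Plek, Cd14, Dppa2 and Trbv13-2 did not pass (adjusted p = 0.23 to 0.651). It was 67 with a replicate block added, where they passed.

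4F embryoid bodies at day 11 had lower expression of heart muscle genes than R1. Tnnt2 was lower at -4.05 ± 0.65 (adjusted p = 0.000121), Actc1 at -4.01 ± 0.76 (adjusted p = 0.000496), Myh6, the alpha myosin heavy chain gene, at -3.09 ± 0.72 (adjusted p = 0.00319) and Tnnc1 at -2.96 ± 0.52. In the list of 33 cardiomyocyte genes 14 were lower and 0 higher, with a mean of -1.30 (camera adjusted p = 6.96e-06; adjusted p = 0.228 with an estimated correlation). Of 20 cardiac progenitor genes 7 were lower and 0 higher, with Tcf21 at -3.70, Wnt2 at -2.47 and Mef2c at -1.71 (-0.86 with the mean of its probe sets; camera adjusted p = 0.0772), while Tbx20 was at -1.18 (adjusted p = 0.213, but -1.46 and 0.00751 with array weights). Vessel and blood genes were lower as well, at 7 of 16 endothelial genes, with Tek at -2.94, Cldn5 at -2.89 and Kdr at -2.20 (camera adjusted p = 0.000159; adjusted p = 0.251 with an estimated correlation), and at 8 of 10 immune genes (9 adjusted over the list alone), with Ctss at -3.79 and Ptprc at -3.23 (camera adjusted p = 1.96e-05; adjusted p = 0.32 with an estimated correlation). Fibroblast genes were lower at 8 of 16, with Lum at -3.68 and Dcn at -3.14 (camera adjusted p = 0.00165; adjusted p = 0.548 with an estimated correlation). The smooth muscle actin gene Actg2 at -5.52 ± 0.64, Colec11 at -4.68, Upk3b at -4.64, Nell1 at -4.53 and Lyz1 at -4.48 were the largest falls. The index of RNA quality was highest in 4F. With the index as a covariate, a fit chosen after the data were seen, Tnnt2 was at -2.07 ± 0.78 (adjusted p = 0.0995) and 10 of the 14 cardiomyocyte genes still passed, with a mean over the 14 of -2.68 against -2.53 without it (mean SE 0.70 and 0.53). The calls of Tek (-0.80, adjusted p = 0.452), Kdr (-1.90, 0.0913) and Mef2c (-1.23, 0.0953) ended with it, and that of Myh6 with only these 6 arrays (0.0784).

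Higher in 4F than in R1 at day 11 were genes of pluripotency, germ line and hypoxia. Tdgf1 was higher by 4.16 ± 0.65 (adjusted p = 8.15e-05), Mael by 4.07 ± 0.33, Fgf4 by 4.04, Mymx by 3.75 and Zfp42 by 3.74 ± 0.47 (adjusted p = 9.02e-06). Pluripotency genes were higher at 14 of 26 (15 adjusted over the list alone) and lower at 1, with Pou5f1 at 2.56 and Nanog at 2.60 (camera adjusted p = 4.15e-13; adjusted p = 0.244 with an estimated correlation). With the index as a covariate 8 of these 15 passed, their mean was 1.69 against 2.32 (mean SE 0.58 and 0.44), and the calls of Pou5f1 (0.73, adjusted p = 0.465), Nanog (1.93, 0.0814) and Tdgf1 (1.85, 0.0918) ended. Germ line genes were higher at 5 of 14, with Ddx4 at 2.94 (camera adjusted p = 4.88e-06; adjusted p = 0.207 with an estimated correlation). Of 13 glycolysis and hypoxia genes 5 were higher and 0 lower, with Ankrd37 at 2.31, Egln3 at 1.60 and Adm at 1.52 (camera adjusted p = 2.94e-05; adjusted p = 0.228 with an estimated correlation). Of 18 endoderm genes 5 were higher and 2 lower, with the apolipoprotein genes Apoc2 at 2.51 and Apob at 2.31 (mean 0.36, median -0.02; camera adjusted p = 0.144). Of 18 imprinted genes 6 were lower and 0 higher, with Grb10 at -2.63 and Nnat at -2.28 (camera adjusted p = 0.00603; adjusted p = 0.497 with an estimated correlation). Eif2s3y was at -3.75 and Xist, the RNA that coats the inactive X chromosome, at 1.65 (adjusted p = 0.000405, but 0.95 and 0.149 with the index and 0.52 with the mean of its probe sets). Where not given, counts adjusted over the list alone were equal. The comparison called 1511 genes, 434 higher and 1077 lower, with groups that did not overlap at 38.9% of genes (10% by chance) and a median change of -0.10 over all genes. Cyclic loess gave 598 higher and 845 lower, and the index 482 and 547.

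4F and 3F at day 11 differed in the same heart and pluripotency lists. Tnnt2 was lower in 4F at -3.98 ± 0.65 (adjusted p = 0.000115), Actc1 at -3.38, Tnni1 at -3.33 and Corin at -3.05. Among 33 cardiomyocyte genes, 11 were lower (13 adjusted over the list alone) and 0 higher, with a mean of -1.19 (camera adjusted p = 8.44e-06; adjusted p = 0.228 with an estimated correlation). Isl1, a transcription factor of cardiac progenitors, was higher in 4F at 1.90, while 6 of 20 members of its list were lower (8 adjusted over the list alone), with Tcf21 at -3.25, Wnt2 at -2.80 and Mef2c at -1.88 (-0.90 with the mean of its probe sets, and adjusted p = 0.059 with only these 6 arrays). Erythroid genes were lower at 7 of 12, with the globin genes Hba-x at -3.91 and Hbb-y at -2.94 (adjusted p = 0.0163, but 0.0694 without 4F replicate 3; camera adjusted p = 0.00017; adjusted p = 0.32 with an estimated correlation). Endothelial genes were lower at 7 of 16, with Tek at -3.53 and Cd34 at -3.19 (camera adjusted p = 4.17e-05; adjusted p = 0.228 with an estimated correlation). Fibroblast genes were lower at 11 of 16 and higher at 2 (camera adjusted p = 0.00106; adjusted p = 0.535 with an estimated correlation). Dppa2 was higher by 5.75 ± 0.39 (adjusted p = 1.52e-09), Zfp42 by 5.40 ± 0.47, Meioc by 5.20, Trap1a by 4.95 and Fgf4 by 4.59 ± 0.50, with 1 of the other probe sets of Fgf4 at -0.48. Of 26 pluripotency genes 15 were higher and 0 lower (camera adjusted p = 3e-10; adjusted p = 0.302 with an estimated correlation), and with the index 4 of the 15 passed, at a mean of 2.20 against 3.11 (mean SE 0.78 and 0.44). Also higher were 7 of 14 germ line genes (camera adjusted p = 1.21e-06; adjusted p = 0.205 with an estimated correlation) and 5 of 13 glycolysis and hypoxia genes (camera adjusted p = 0.000154; adjusted p = 0.251 with an estimated correlation). Nell1 at -6.27 ± 0.40, Actg2 at -5.52, Upk3b at -4.85, Nepn at -4.62 and Colec11 at -4.59 were the largest falls. Where not given, counts adjusted over the list alone were equal. The index of RNA quality was higher in 4F. The comparison called 1824 genes, 931 higher and 893 lower, with groups that did not overlap at 29.6% of genes (10% by chance) and a median change of -0.12. Without 3F replicate 1, 564 were higher and 1172 lower, array weights gave 801 and 1178, and quantile normalization 990 and 1144. The split was the other way at 1325 to 1034 and 1081 to 750 without 3F replicates 2 and 3, 1738 to 1177 with all probe sets and 785 to 320 with the index, and is left open. The count was 840 with only these 6 arrays in the fit and 1105 with the index, where Tnnt2 was at -0.96 ± 1.02 (adjusted p = 0.585) and 4 of the 11 cardiomyocyte genes passed. The mean of those 11 was -2.25 with the index and -2.40 without, 10 kept their sign, and the mean SE was 0.77 and 0.45. The index also ended the calls of Tek (-0.26, adjusted p = 0.858), Actg2 (-2.01, 0.162), Colec11 (-1.84), Corin (-1.16), Tnni1 (-2.19), Cd34 (-1.92), Mef2c (-1.15) and Isl1 (1.12). Those of Tcf21 (-2.73, 0.0991), Hbb-y (-2.54 ± 1.73) and Actc1 (-4.62 ± 1.43, 0.0544) ended with a fold near to or above that without it.

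The change from day 0 to day 11 was then compared between lines, as a difference of differences. For 3F against R1 the difference in Tnnt2 was 0.07 ± 0.93 (adjusted p = 0.972), and of 33 cardiomyocyte genes 2 differed downward and 1 upward (mean -0.07, median 0.09; camera adjusted p = 0.223). Immune genes differed downward in 3F at 3 of 10 (8 adjusted over the list alone), with Ptprc at -3.62 ± 0.64 (adjusted p = 0.00358) and Cd14 at -2.66 (camera adjusted p = 1.52e-05; adjusted p = 0.32 with an estimated correlation). The largest upward differences were Trbv13-2 at 3.95, Khdc3 at 3.08, Dpys at 4.89 ± 0.39, Aass at 4.65 and Fmr1nb at 3.41. The last 3 were lower in 3F at day 0. Most downward were Ppbp at -4.45, Ptprc, Plek at -3.57, C1qb at -3.54 (adjusted p = 0.0452) and Mpeg1 at -3.26 (adjusted p = 0.0229). Single arrays left out ended the calls of C1qb in 8 and of Mpeg1 in 6 of 12 fits. With only the compared arrays Ptprc (0.0754) and Trbv13-2 (0.0725) did not pass either. The test called 272 genes, 50 higher and 222 lower. The count was 1054, 108 and 150 without R1 day 0 replicates 1, 2 and 3, and 139, 133 and 418 without those of R1 day 11. It was 148 and 101 without 3F day 0 replicates 1 and 3, and 117 and 1264 without 3F day 11 replicates 1 and 3.

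For 4F against R1 the change differed in genes of muscle, stroma and pluripotency. The difference was -4.30 ± 0.93 in Tnnt2 (adjusted p = 0.0038), -3.19 in Tnnc1 and -2.39 in Corin. In the list of 33 cardiomyocyte genes 9 differed downward (10 adjusted over the list alone) and 0 upward (camera adjusted p = 0.000723; adjusted p = 0.362 with an estimated correlation). Ifit1 at -6.28 ± 0.58 (adjusted p = 1.14e-06), Usp18 at -5.16 and Dcn at -5.29, all higher in 4F at day 0, differed most downward. So did Lum at -5.31 and Actg2 at -5.22. The list of fibroblast genes held 8 such genes of 16 (9 adjusted over the list alone; camera adjusted p = 0.000169; adjusted p = 0.49 with an estimated correlation). The immune list held 7 of 10 (9 adjusted over the list alone; camera adjusted p = 2.26e-05; adjusted p = 0.32 with an estimated correlation) and the endothelial list 5 of 16 (6 adjusted over the list alone; camera adjusted p = 0.00281; adjusted p = 0.364 with an estimated correlation). Pluripotency genes fell less in 4F at 8 of 26, with Tdgf1 at 4.02 ± 0.91, Zfp42 at 3.44, Dppa2 at 3.45 and Pou5f1 at 2.62 (adjusted p = 0.0191, but 0.0557 without R1 day 11 replicate 3 and 0.055 and 0.0557 without 4F day 11 replicates 1 and 2; camera adjusted p = 1.79e-06; adjusted p = 0.44 with an estimated correlation). The same 8 passed adjusted over the list alone. AF067061 at 4.94, Gdap10 at 4.32, Rpl39l at 3.95 and Mael at 3.84 were the other largest upward differences. The test called 1728 genes, 449 higher and 1279 lower, and cyclic loess gave 698 and 928. The count was 993 without 4F day 11 replicate 1 and 246 with the index, where Tnnt2 was at -1.94 ± 1.01 (adjusted p = 0.424), 2 of the 9 cardiomyocyte genes passed (mean -1.84 against -2.42) and 0 of the 8 pluripotency genes (1.48 against 2.90), and Tnnc1 (-3.53, 0.0812), Actg2 (-2.48), Gdap10 (1.97) and Rpl39l (1.75) did not.

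For 4F against 3F the change differed in cardiomyocyte, endothelial and pluripotency genes. Tnnt2 was at -4.37 ± 0.93 (adjusted p = 0.00456), Tnni1 at -3.20, Corin at -3.07 and Myh7 at -2.79. Among 33 cardiomyocyte genes, 8 differed downward (11 adjusted over the list alone) and 0 upward (camera adjusted p = 8.44e-06; adjusted p = 0.228 with an estimated correlation). Endothelial genes differed downward at 8 of 16, with Cd34 at -3.24 (camera adjusted p = 1.31e-05; adjusted p = 0.218 with an estimated correlation). Erythroid genes differed downward at 5 of 12, with Hba-x at -4.02 (camera adjusted p = 0.000135; adjusted p = 0.32 with an estimated correlation). Fibroblast genes differed downward at 3 of 16 and upward at 2, and immune genes at 0 of 10. Of 9 p53 targets 3 differed upward, with Mdm2 at 1.64 (camera adjusted p = 1.39e-06; adjusted p = 0.226 with an estimated correlation). Pluripotency genes differed upward at 10 of 26 and downward at 1 (10 and 2 adjusted over the list alone), with Dppa2 at 5.52 ± 0.56, Zfp42 at 4.94, Fgf4 at 4.33 and Tdgf1 at 4.08 (camera adjusted p = 2.96e-06; adjusted p = 0.445 with an estimated correlation). Trap1a at 4.25 was also among the largest upward differences. Nell1 at -6.53 ± 0.57, Upk3b at -4.73 and Nepn at -4.58 were the largest downward, with Ifit1 at -4.91 and Rtp4 at -4.80, both higher in 4F at day 0. The test called 1167 genes, 620 higher and 547 lower. The split was 406 to 723 without 3F day 11 replicate 1, 710 to 909 with array weights, 668 to 809 after quantile normalization, 537 to 580 after median centring and 794 to 300 with the index, so its direction is left open. With the index Tnnt2 was at -1.92 ± 1.03 (adjusted p = 0.26), and 3 of the 8 cardiomyocyte genes (mean -1.81 against -2.36) and 4 of the 11 pluripotency genes passed (1.97 against 3.11), and Cd34 (-2.21), Corin (-1.54), Tdgf1 (1.23) and Tnni1 (-2.28) did not.

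**Figure D3:**
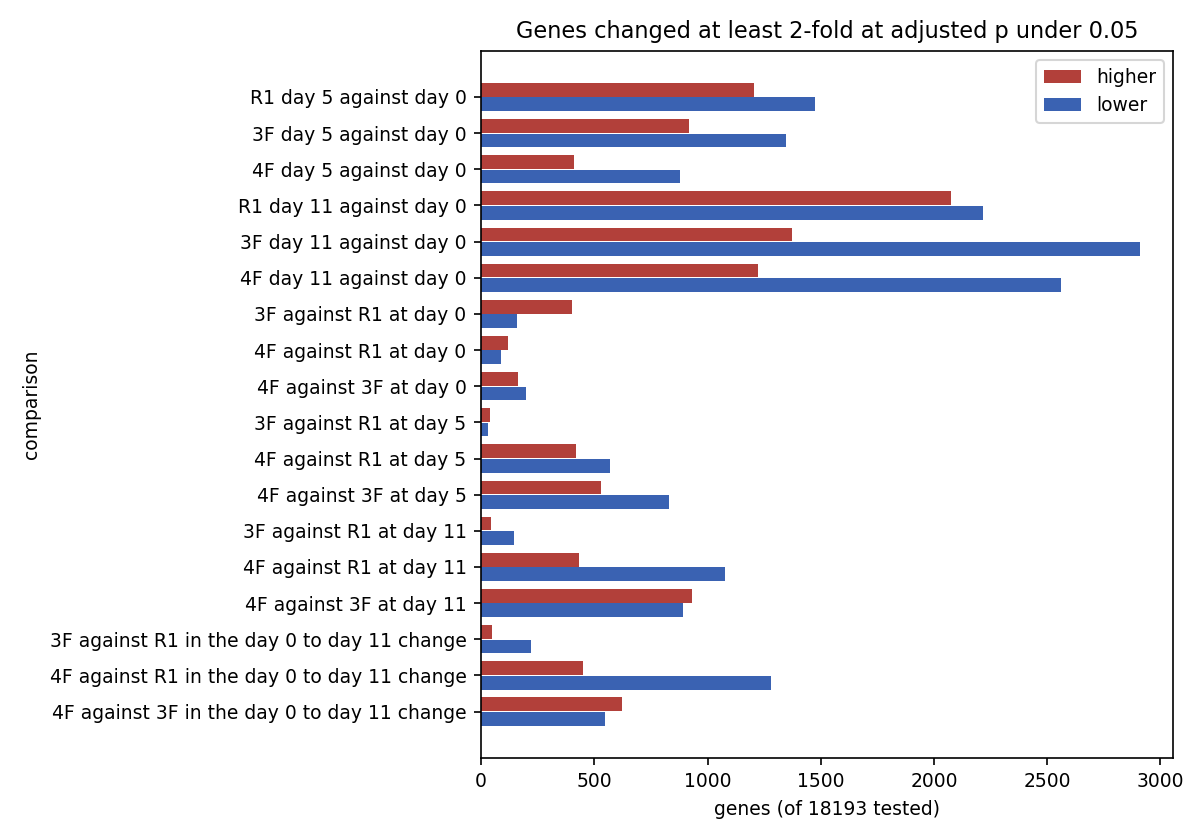
Number of genes called higher and lower in each of the 18 comparisons, of 18193 genes tested, at an adjusted p under 0.05 and a change of at least 2-fold, with bars starting at 0. Differences of 3F from R1 were called at 68 genes at day 5 and 185 at day 11, and those of 4F from R1 at 992 and 1511.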

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

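The 5 tests of explanations below were chosen after the results were seen, and the groupings of arrays were fixed before. The change from day 0 to day 11 differed between lines by a test of the difference itself: 272 genes for 3F against R1, 1728 for 4F against R1 and 1167 for 4F against 3F. Of 100 groupings of the same arrays, 5, 3 and 9 called at least as many genes, the real one included, with highest other counts of 1244, 2288 and 2897. The highest groupings for 4F against R1 and for 4F against 3F kept the arrays of whole lines together at day 11. Such groupings hold the structure of the samples rather than chance alone. These counts therefore cannot decide about chance, which was not excluded in any of the 3 comparisons.

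Cardiomyocyte genes were lower in 4F than in R1 at day 11, and those 4F arrays also had the highest 3' minus 5' index. Lower RNA quality could lower such genes. With the index as a covariate the mean over the 14 lower genes, of which 10 passed, was -2.68, against -2.53 without it. The index of 4F at day 11 (2.44 to 2.89) overlapped no other group, so RNA quality cannot be told from group or set aside. The call of Tnnt2 ended (-4.05 ± 0.65 before, -2.07 ± 0.78 with an adjusted p of 0.0995 after). For the change in 4F against R1, 2 of 9 passed (mean -1.84 against -2.42) and 1728 genes became 246. For 4F against 3F, 4 of 11 passed at a mean of -2.25 against -2.40 (mean SE 0.77 against 0.45). A mixture of undifferentiated cells with cells differentiated as in R1 would give 1 share for both gene groups. The shares were 95.2% from cardiomyocyte and 7.07% from pluripotency genes, 88.17 points apart, unlike such a mixture. The cause is left open.

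At day 5, replicate 3 of 4F lay nearer to R1 and 3F than replicates 1 and 2. If it were a mislabelled array of another line, genes that separate the lines would place it near 100% of the way, but the median was 45.17% (quartiles 24.61 to 52.25). The limit of 75% on the upper quartile was added after the value was seen. If cells of R1 had been mixed in, the Y-linked gene Eif2s3y should give the same share as other genes. This 1 gene gave 12.6% against a median of 39.0%, 26.39 points apart. Cells of 3F and other causes were not tested.

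In the same array Eif2s3y was higher by 2.41 than in replicates 1 and 2, and RNA of male feeder cells could raise it. The median difference over 16 fibroblast and feeder genes was 0.03 (quartiles -0.37 and 0.40), so the median did not rise. The source of that signal was not found.

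Groupings of 3 against 3 arrays number 10 and cannot fall under 0.05. For counts of called genes, 1 of 10 (the real one) reached the real count in R1 at day 5 (2679, highest other 0), 3F at day 5 (2263, 0), 4F at day 5 (1286, 9), R1 at day 11 (4294, 0), 3F at day 11 (4285, 0) and 4F at day 11 (3784, 0). It was also 1 at day 0 for 3F against R1 (562, 0), 4F against R1 (204, 51) and 4F against 3F (360, 1), at day 5 for 4F against R1 (992, 85) and 4F against 3F (1360, 26), and at day 11 for 4F against R1 (1511, 7) and 4F against 3F (1824, 457). It was 2 for 3F against R1 at day 5 (68, 101) and at day 11 (185, 423). For the absolute mean of the cardiomyocyte list it was 1 in R1 (1.24, 0.85) and 3F (1.17, 0.60), 10 in 4F (0.07, 0.15), 8 for 3F against R1 (0.11, 0.65), and 1 for 4F against R1 (1.30, 0.99) and 4F against 3F (1.19, 0.73), all at day 11.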

How the results depend on the processing

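Tests with quantile normalization, replicate 3 of all groups left out, the index and a block with only the compared arrays were chosen after the results were seen. For the 429 values of genes looked at, 9139 alternative values kept direction and side of the threshold in 8703 cases, lost the call in 379, gained it in 26 and reversed in 31. Single arrays left out ended the calls of 42 gene values in 159 fits. Among them, the text leaves out Eomes and Smarcd3 in 4F at day 5, Myl2 in 3F at day 11, Fbln2, Col6a3 and Sycp3 for 3F against R1 at day 0, Klf4 for 4F against R1 at day 0, and Nr5a2, Tcl1, Col6a3, Peg3 and Eif2s3y for 4F against 3F at day 0. It also leaves out Tex19.1 for 3F against R1, Otx2 and Actn2 for 4F against R1 and Actc1 for 4F against 3F at day 5, Ctss and Tyrobp for 3F against R1 at day 11, and Ankrd1, Ldb3 and Myom2 (3F against R1) and Kdr (4F against 3F) for the change to day 11. In 13 of 15 comparisons the replicates share only a number, and a block over all 27 arrays moved no count by over 1.5 times. Arrays with a group of 2 left assume that group to vary like the others. The cause was not tested, except where fewer arrays, more probe sets or another threshold are the alternative itself. Signal near background limits genes that the dim filter takes out.

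The mean of probe sets gave 331 and 44 genes for 3F against R1 at days 0 and 5. All probe sets gave 136 and 293 for 3F against R1 at days 5 and 11, 2477 and 2885 for 4F against R1 and 3F at day 11, and 2831 and 1774 for the change to day 11 in 4F against R1 and 3F. With no fold minimum the counts were 6492, 5483 and 3918 at day 5 and 8237, 8693 and 7878 at day 11 in R1, 3F and 4F. Between lines (3F against R1, 4F against R1, 4F against 3F) they were 1311, 391 and 772 at day 0, 118, 2273 and 3107 at day 5, 451, 4507 and 5545 at day 11, and 2803 and 1800 for the change in 4F against R1 and 3F. At an adjusted p under 0.01 they were 260, 123 and 217 at day 0, 42 and 113 for 3F against R1 at days 5 and 11, and 68, 942 and 596 for the change. With treat they were 233, 116 and 192, 35 and 106, and 84, 1100 and 693 in that order. Only the compared arrays gave 134 for 4F against R1 at day 0, 10 for 3F against R1 and 840 for 4F against 3F at day 11 and 80 for the change in 3F against R1. Array weights gave 1158, 404 and 615 at day 0, 220 for 3F against R1 at day 5, and 778 and 2606 for the change in 3F and 4F against R1. Without replicate 3 of all groups there were 184 for 3F against R1 and 238 for 4F against 3F at day 0, and 391 for 3F against R1 at day 11. The index gave 193 for 3F against R1 at day 0, 1105 for 4F against 3F at day 11, and 728 and 246 for the change in 3F and 4F against R1. Quantile normalization gave 161 for the change in 3F against R1, and the block with only the compared arrays gave 67 for 3F against R1 at day 11.

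Leaving out single arrays gave 193 to 1179, 131 to 449 and 192 to 461 genes at day 0 (3F against R1, 4F against R1, 4F against 3F), 39 to 91, 665 to 1420 and 1006 to 1797 at day 5, and 115 to 512, 1084 to 2199 and 1477 to 2360 at day 11. For the change it gave 101 to 1264, 993 to 2508 and 849 to 1639. Within lines it gave 2359 to 2913, 2176 to 2308 and 1215 to 1324 at day 5 and 4049 to 4458, 4095 to 4525 and 3533 to 3953 at day 11 (R1, 3F, 4F). The genes shared by 3F and 4F against R1 at day 0 numbered 37 to 190, and 130 with no fold minimum.

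With an estimated correlation the cardiomyocyte list no longer passed at day 11 in R1 (mean 1.24, adjusted p = 0.364), 3F (1.17, 0.32), 4F against R1 (-1.30, 0.228) or 4F against 3F (-1.19, 0.228), by limma's camera. Single arrays left out gave 1.04 to 1.55, 1.01 to 1.31, -1.60 to -1.09 and -1.32 to -1.03. For 3F against R1 at day 11 they gave -0.42 to 0.09, around a mean of -0.11. The mean in 4F at day 11 (0.07) was -0.01 as a median, -0.05 after centring, -0.06 without replicate 3 of all groups, -0.14 with the index, and -0.04 to 0.13 without single arrays.

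The named genes that reversed were not called in that comparison. In 4F against 3F at day 11 the index also turned unnamed called genes. Single arrays left out gave Actc1 at -1.93 to 0.07 for 3F against R1 at day 11 and -0.17 to 1.0 in 4F at day 11, Mesp1 at -0.61 to 0.76 for 3F against R1 at day 5, Myh6 at -0.17 to 2.05 in R1 at day 11, Pou5f1 at -0.19 to 0.01 for 3F and -0.19 to 0.04 for 4F against R1 at day 0, and Tbx20 at -0.27 to 1.59 in 4F at day 5. They gave Tnnt2 at -0.25 to 0.17 for 3F against R1 at day 11 and -0.11 to 0.31 for the change. The index turned Actc1 in 4F at day 11 to -0.91, Pou5f1 for 3F and 4F against R1 at day 0 to 0.79 and 0.29, Tbx20 for 3F against R1 at day 5 to -0.56 and for 4F against R1 at day 11 to 0.43. It turned Tnnt2 to -0.53 for 3F against R1 at day 5, to -0.02 for the change in 3F against R1 and to 0.56 in 4F at day 5. Without replicate 3 of all groups, Actc1 in 4F at day 11 was at -0.31, Mesp1 for 3F against R1 at day 5 at -0.75, Tbx20 in 4F at day 5 at -0.34 and Tnnt2 for the change in 3F against R1 at -0.11. Array weights gave Mesp1 at -0.24 and, for 3F against R1 at day 11, Tnnt2 at 0.14. Tnnt2 there was 0.04 with the mean of probe sets and 0.10 after quantile normalization, which also gave Pou5f1 in 4F at day 5 at 0.08.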

Other observations

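Several lists fixed beforehand are not described above, and no test here was chosen after the result was seen. Of 10 smooth muscle genes 5 fell and 0 rose by day 5 in each line, with means of -1.28 in R1, -1.87 in 3F and -1.56 in 4F. Of 16 fibroblast and feeder genes 9, 13 and 14 fell there too, so the cells behind it are left open. At day 11 4 smooth muscle genes were lower in 4F than in R1 (mean -1.37) and than in 3F (-1.26), with 0 higher. Of 13 extracellular matrix genes 5 were lower and 0 higher in 4F than in R1 at day 5 (mean -0.97), and 7 lower and 2 higher than in 3F (-0.81). Of 12 Notch genes 6 were lower and 1 higher in 4F than in 3F at day 5. Of 13 Wnt genes 4 rose by day 5 in R1 and in 3F, and 1 in 4F.

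Of 19 neural genes 4, 5 and 5 fell by day 11 in R1, 3F and 4F, and 0, 0 and 1 rose. Of 7 trophoblast genes 3 rose by day 5 in R1 and 2 each in 3F and 4F. Of 6 reprogramming factor genes 4 fell by day 11 in R1 and 5 each in 3F and 4F, and 2 were higher in 4F than in R1. Of 5 two-cell-like genes 2 were higher in 4F than in R1 (mean 0.75) and than in 3F (0.80) at day 11. Of 10 skeletal muscle genes 1 rose and 2 fell by day 11 in R1 and in 4F, and 2 and 2 in 3F. Of 15 fatty acid oxidation and mitochondrial genes 1 rose and 3 fell by day 11 in R1, 0 and 3 in 3F and 0 and 2 in 4F.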
